A study of uncultured soil microorganism with 73 samples.

How the data were processed

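Soil DNA from 73 samples of 6 sites on Shennongjia Mountain was measured on GeoChip, a glass array whose probes are short stretches of microbial genes with known functions. Per the labels, each sample was a mix of soil cores from the top 10 cm of a plot, and the DNA was labelled with Cy5. The site codes and the replicate numbers were taken from the sample titles, and the elevation ranges from the labels. Apart from those of trends, p-values measure the spread between plots, as far as each sample is a plot of its own. The p-values of trends rest on the scatter of the 6 site means. Elevation was given as a range per site and not per sample, so a relation with elevation rests on 6 site means. Vegetation, climate and soil can differ between the same sites and were not given.

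The labels contradict each other in 2 places. The source name places the soil in Tibetan grasslands, while the series title and the sampling text name Shennongjia Mountain. The sampling text gives 12 plots per site, while the sites hold 5, 8 or 15 samples, so it is unknown which samples share a plot. The tests count the samples of a site as independent, and samples of a shared plot would make their p-values too small.

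The deposited table holds 1 intensity per probe and sample for 64314 probes, each with a gene name, 1 of 14 functional categories and, for most, the lineage of the organism the probe was designed from. The intensity values are linear, lie between 619 and 2340747, and include no 0. Blanks made up 39.3% of the values and were read as probes not detected. The authors do not state the scanner, the background correction, the rule for calling a probe detected or the normalization. The column totals differed 14.0 times between the highest and the lowest sample, so the columns were not at a common total. For 1448 probes no lineage was given. An array gives no counts. The number of samples and probes limits the precision given here, and so may the unstated background and normalization.

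Each intensity was divided by the sum over all probes of its sample and multiplied by 100, which gives a percent of total signal. A gene family is the set of probes with the same gene name, and its value is the log2 of its summed percent. Families needed at least 5 probes, which kept 528 of the 724 gene names and left out 196 families. A pseudocount of 1.323e-04 percent, 0.5 times the smallest family value above 0, was added to the 36 families that had a sample at 0, and to no other family. Signal on an array is not a cell or gene count, and a share can move because other shares move.

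Families were compared with limma 3.58.1 in R 4.3.3, in a single fit of all 73 samples with site as a factor of 6 levels. The contrasts were the highest site against the lowest, the 5 steps between sites next to each other in elevation, and the moderated F test over all sites. A trend was fitted with limma on the 6 site means as a slope per 1000 m of the midpoint of each range. A family was called at a Benjamini-Hochberg adjusted p under 0.05 over all families of a comparison. A permutation test per family was run beside limma, exact where a site had under 10 samples and with 100000 resamples otherwise. Detected probes, Shannon diversity (natural log, over shares of signal) and the shares of gene lists, categories and domains were compared with 2-sided permutation tests of the same kind. For site means, Pearson r and Spearman rho were given with exact permutation p over all pairings of the 6 means with the 6 elevations. Intervals for differences of shares, probes and diversity are 95% bootstrap intervals from 10000 draws. Community structure was tested with adonis2, a permutation test of dissimilarities, in vegan 2.7.1 on Bray-Curtis dissimilarity, with betadisper for the spread within sites. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

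The comparisons, the gene lists and the rule for naming genes were set before the data were examined. In each comparison the rule names the called families with the largest differences, up to 5 in each direction for the highest against the lowest site and up to 3 in the steps. For the highest against the lowest site it also names 22 marker genes, of which chitinase was not in the table, and up to 4 members of each list with the smallest p. For the trend it names the 5 families with the smallest p in each direction. Families named beyond this rule were chosen after their values were seen, and the text says so where it names them.

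There were 24 gene lists, matched by name without regard to case, spaces, hyphens or low lines. Names missing from the table included amoB, nxrA, nxrB and hzsA of nitrification, hdrB and mtmB of methane cycling, and merA of metal resistance. The pectin list kept 1 of 10 names, and the list for methanogenic archaea kept mcrA alone. The lists overlap, since mcrA stands in 2 lists and several fungal enzymes stand both in the fungal list and in a degradation list. The name alkB in the metal and the aromatic lists is filed by the table under hydrocarbon degradation, catB of the antibiotic list is filed under organic remediation, and glnA is filed under stress. No cells were sorted, and the lists for fungi and methanogenic archaea served as markers of those organisms. Adjusted p-values for shares were computed over the 24 lists, over the 14 categories and over the 6 domain sets separately. The written plan left open whether lists and categories form one family of tests, and both results are given.

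The tests were checked on simulated data made from these samples with shuffled sites and 200 of 528 families changed. Recovery with only a few families changed was not simulated, and the adjusted threshold is harder to pass then. For the highest against the lowest site, limma recovered 36.5% of families changed 1.1-fold, 86.8% of those changed 1.5-fold and 96.3% of those changed 2-fold, and 4.07% of its calls were false. For LK against JC it recovered 78.2% at 1.5-fold, with 3.04% of calls false. The F test over 6 sites recovered 89.7% at 1.5-fold with 1.68% of calls false. The trend recovered 94.5% at 1.5-fold per unit of elevation in its slope, with 3.83% of calls false. That fold is not a fold between sites, so the recovery of the trend cannot be set beside that of the other tests. For 2000 sets of random normal values in place of the samples' own, 4.55% of permutation p-values for GM against JC lay under 0.05. This rate was not computed on the samples' own values. adonis2 called 12 of 20 simulated sets in which 5000 probes were doubled at 1 site, and 1 of 20 without a change.

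Alternatives set before the data were examined covered the scaling between samples, how probes are combined, filters on rarely detected probes and small families, the pseudocount, limma's settings, a permutation test, blocks, other elevations, other dissimilarities and samples left out in turn. Others were added after seeing the data. The highest and the lowest site were also compared without each JC sample in turn. In 10 samples the summed intensity was above 1000 in units of 1000000. Detected probes, diversity, shares at GM and JC, families in limma and community structure over all sites were also computed without them. Pairs of sites, the spread within sites, permutation tests per family and trends of list shares, detected probes and diversity were not. Another 10 samples had a score above 0.2 on the first principal component of probe signal, and the same results were also computed without those. Families and community structure were also fitted with both sets as terms, where the second term comes from the same probe values and makes p-values too small, and with the number of detected probes as a term. No sample was left out of the results given first.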

Results

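The data describe the functional genes of soil microbes at 6 elevations of Shennongjia Mountain, and the series asks how their structure changes along the gradient. Site JC lay at 1057 to 1059 m and gave 8 samples, and LK lay at 1575 to 1715 m and gave 5. JH (1725 to 1844 m), HJ (2243 to 2350 m), LS (2456 to 2632 m) and GM (2720 to 2776 m) gave 15 samples each. A sample had signal on 23821 to 53257 of the 64314 probes, and 6891 probes had signal in all 73 samples. The summed intensity per sample, in units of 1000000, ran from 200.57 to 2817.9, and 10 samples lay above 1000 (2 of JC, 1 of JH, 4 of HJ and 3 of GM). In the other 63 samples it was at most 648.62.

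The soils shared a broad functional make-up dominated by probes from bacteria, which took 87.6% ± 0.737 of the signal (SD, n = 73). Probes from Proteobacteria took 52.9% ± 0.754, from Actinobacteria 15.7% ± 0.528 and from the fungal phylum Ascomycota 5.90% ± 0.403. The genera with the largest shares among those with the most probes were Burkholderia with 4.21% ± 0.210 and Pseudomonas with 3.33% ± 0.118, followed by Mycobacterium with 2.94% ± 0.127 and Streptomyces with 2.87% ± 0.158. Among functions, the category of organic remediation, genes that break down pollutants and other organic compounds, took 24.7% ± 0.422 and stress genes 21.0% ± 0.162. Carbon cycling took 13.4% ± 0.353, metal resistance 12.0% ± 0.112 and nitrogen cycling 8.09% ± 0.263. Families with many probes weighed most, such as pimF, filed under organic remediation, with 2.95% ± 0.108, and narG, the nitrate reductase that starts denitrification, with 1.66% ± 0.168. The shares depend on how many probes the array holds for a group and are not shares of cells.

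The first question was whether soils at different elevations held different numbers of functional genes. JC had signal on 37959 ± 4771 probes (SD, n = 8), LK on 40900 ± 11257 (n = 5), JH on 40699 ± 5992, HJ on 37572 ± 7375, LS on 36429 ± 6394 and GM on 41268 ± 7335 (n = 15 each). The sites did not differ beyond the spread between plots (permutation F test, p = 0.349, adjusted p = 0.611 over 7 tests). GM exceeded JC by 3309 probes (95% interval -1496 to 8015, exact permutation p = 0.263). The step with the smallest p was GM against LS, with 4839 more probes at GM (permutation p = 0.0644, adjusted p = 0.451). Shannon diversity ran from 10.13 ± 0.151 at HJ to 10.22 ± 0.141 at GM (SD, n = 15) and did not differ among the sites (permutation F test, p = 0.523). Over the 6 site means, detected probes had a Pearson r of -0.0301 with elevation (exact permutation p = 0.951) and a Spearman rho of 0.0286 (p = 1). Without JC and GM, the sites farthest from the median elevation, r over the remaining 4 sites was -0.995. No p was computed for it, and so few points cannot show a decline. For Shannon diversity r was -0.0339 (exact permutation p = 0.956) and rho 0.0857 (p = 0.919), and without the same sites r was -0.962, again with no p computed.

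**Figure D1:**
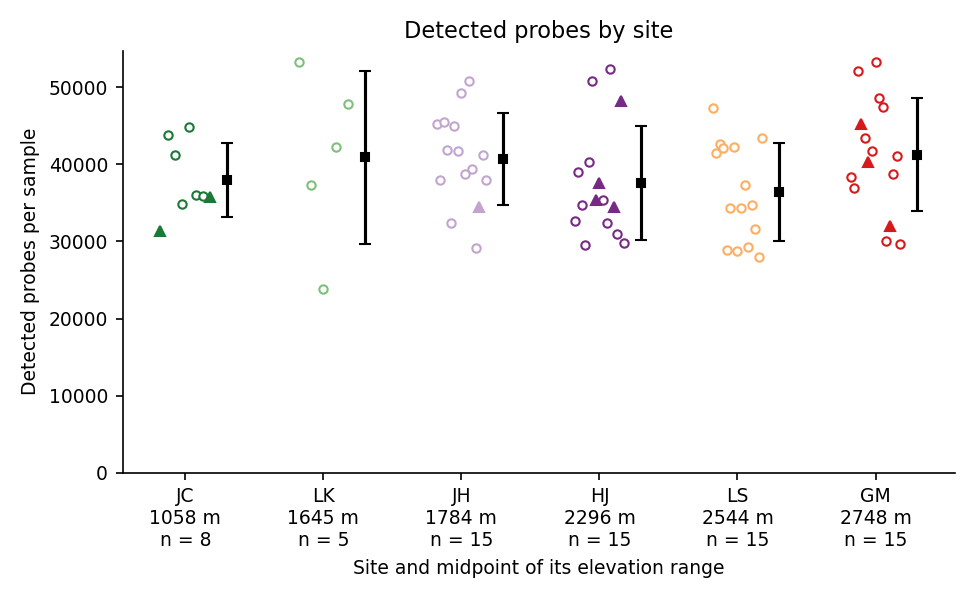
Number of probes with signal in each sample (y axis) by site, from the lowest to the highest elevation (x axis). Circles are samples, triangles the 10 samples with a summed intensity above 1000 units, and black squares with bars the mean and SD of a site, from 36429 at LS to 41268 at GM.

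The next question was whether the composition of functional genes differed among sites. Samples of a site were about as unlike each other as samples of different sites, with a mean Bray-Curtis dissimilarity of 0.272 within sites and 0.274 between them. Site accounted for 8.52% of the variation among samples, where 6.94% is what shuffled sites give on average (vegan's adonis2, permutation p = 0.145). The spread within sites did not differ beyond chance (betadisper, permutation p = 0.506), with mean distances to the site centre from 0.166 at JC to 0.20031 at LS. Of the 15 pairs of sites, JC and LS had the smallest p (R2 9.37%, permutation p = 0.0272), followed by LS and GM (7.00%, p = 0.0480) and JH and LS (6.73%, p = 0.0501). The adjusted p was 0.251 for each of these pairs. On probes with signal in all samples, 10 samples stood apart on the first principal component, which held 30.1% of the variance. They were 1 sample of JH and 3 each of HJ, LS and GM. Without them site accounted for 11.7% of the variation in the remaining 63 samples, where shuffled sites give 8.06% on average (permutation p = 0.0261). It accounted for 6.82% with these and the samples of high summed intensity as terms (p = 0.0847), 6.83% with the number of detected probes as a term (p = 0.214) and 9.33% without the samples of high summed intensity (p = 0.214), all alternatives chosen after seeing the data. The 9.33% also rests on 63 samples, where shuffled sites give 8.06% on average. For the fits with terms no such average was computed, so their shares cannot be set beside 6.94%.

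**Figure D2:**
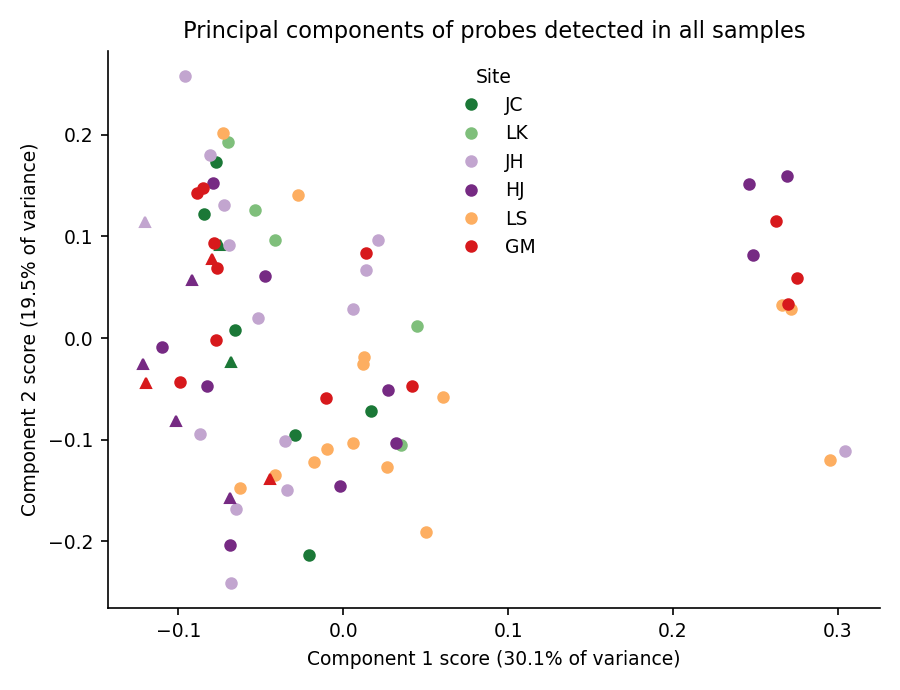
Scores of the 73 samples on the first component (x axis, 30.1% of variance) and the second component (y axis, 19.5%) of the 6891 probes with signal in all samples, coloured by site. Triangles are the samples with a summed intensity above 1000 units, and 10 samples from 4 sites score above 0.2 on the first component.

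At GM and JC, the ends of the gradient, most gene families held near shares of the signal, and the 95% interval of the difference lay within 1.5-fold for 449 of 528 families. Of these families 0 passed the adjusted threshold in limma, where 47 had an unadjusted p under 0.05 (35 higher and 12 lower at GM) and 26.4 are expected by chance. The permutation test per family also called 0, with 62 at an unadjusted p under 0.05. The median 95% interval of a family reached 0.18 on the log2 scale to either side. The 5 families with the smallest p were named after their values were seen. The terminase large subunit family, the motor that packs phage DNA, took 0.0199% ± 0.00245 of the signal at GM (SD, n = 15) and 0.0160% ± 0.00213 at JC (n = 8), a log2 difference of 0.32 (95% interval 0.16 to 0.47, limma adjusted p = 0.0923, above the JC mean in 14 of 15 samples). Next came nagK, filed under organic remediation, with a log2 difference of -0.09 (adjusted p = 0.344), followed by the capsid family major_capsid_protein with 0.29, the plant virus coat family coat_unassigned_Secoviridae with 0.69 and UvsW, a phage helicase, with 0.81 (adjusted p = 0.346 each). Probes of RNA viruses, to which Secoviridae belong, had signal in 43.45% of their values although genomic DNA was measured. In alternatives chosen after seeing the data, terminase_large_subunit was called without JC replicate 3 (0.35, limma adjusted p = 0.0279), while 0 families were called without any other JC sample, and terminase_large_subunit (0.33, adjusted p = 0.0386) and nagK (-0.11, adjusted p = 0.0328) were called without the 10 samples apart on the first component. The values of terminase_large_subunit and UvsW stayed above 0 under each scaling that could be computed for them. The sign of nagK turned without scaling, where the median family lay at 0.21, and those of major_capsid_protein and coat_unassigned_Secoviridae turned with the mean over detected probes, where the median family lay at -0.13. Of the 89 families named in this comparison, 30 had the other sign without scaling, 18 with scaling to the median of shared probes and 51 with the mean over detected probes, as did 25 of 79 with quantile normalization.

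Nitrogen cycling genes gave no calls between GM and JC, and the differences of the members named here were at most 0.21 on the log2 scale. The nitrogen fixation marker nifH, a nitrogenase subunit, took 1.15% ± 0.0823 of the signal at GM (SD, n = 15) and 1.09% ± 0.0739 at JC (n = 8), a log2 difference of 0.08 (95% interval -0.02 to 0.17, limma adjusted p = 0.633). All 3 tested members of the nitrification and anammox list had values above 0, among them amoA of ammonia oxidation with 0.03, hao of hydroxylamine oxidation with 0.09 and hzo with 0.21. All 5 denitrification genes also had values above 0, each within 0.04 of it, with narG at 0.02, nirK at 0.01, nirS, the other nitrite reductase, at 0.03, norB at 0.03 and the nitrous oxide reductase nosZ at 0.03. Nitrate and nitrite reduction to ammonium or biomass had 3 members above and 3 below 0, including nrfA, which makes ammonium from nitrite, at -0.07 (-0.0046 without JC replicate 1), nasA at 0.06, nirA at 0.09 and napA at 0.05. In ammonification and ammonium assimilation, gdh of glutamate dehydrogenase was at 0.13, the urease gene ureC at -0.02 and the glutamine synthetase gene glnA at -0.02. Adjusted over the list alone, each of these 5 lists had 0 called members, as over all families, and 0 members had an unadjusted p under 0.05. With the mean over detected probes amoA, narG, nirK, nirS, nosZ, nifH, hao, hzo, norB, nasA, nirA, napA and gdh were below 0, and without scaling nrfA, ureC and glnA were above 0. Of these nirS, napA and gdh were below 0 with quantile normalization too. Scaling to the median of shared probes also put ureC and glnA above 0.

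Of the 3 methane genes 2 had values above 0 at GM against JC, and 0 passed the test. The methane oxidation marker pmoA took 0.137% ± 0.0109 of the signal at GM (SD, n = 15) and 0.122% ± 0.0121 at JC (n = 8), a log2 difference of 0.16 (95% interval 0.02 to 0.30, limma adjusted p = 0.420), and lay above the JC mean in 13 of 15 samples. The methanogenesis marker mcrA, the single member of the list for methanogenic archaea, was at 0.13 (adjusted p = 0.567), and mmoX, the soluble methane monooxygenase, at -0.09. With the mean over detected probes pmoA and mcrA were below 0, and without scaling mmoX was above 0. Adjusted over the list alone, the lowest p was 0.0691 for methane cycling and 0.0927 for the methanogen list, so 0 members were called in either, and 1 methane member had an unadjusted p under 0.05.

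Genes that fix carbon and break down plant and fungal polymers gave no calls between GM and JC. Carbon fixation had 1 member above 0, aclB of the reverse citric acid cycle at 0.15, and 4 below, including pcc at -0.07, FTHFS at -0.07 (0.13 without JC replicate 1), rubisco at -0.01 and CODH at -0.0022. In starch degradation 5 of 8 members were above 0, with amyX at 0.28, isopullulanase at 0.22, nplT at -0.07, apu at 0.10 (0.01 without JC replicate 7) and the alpha-amylase gene amyA at -0.01. Hemicellulose degradation had 4 of 5 members above 0, among them ara_fungi at 0.08, xylanase at 0.03, xylA at 0.01 and mannanase at -0.03. Cellulose degradation had 3 of 4 above 0, with exoglucanase at 0.07, endoglucanase at 0.03, cellobiase at 0.02 and CDH, cellobiose dehydrogenase, at -0.05. Chitin degradation had 3 of 4 above 0, with acetylglucosaminidase at 0.04, chitin_deacetylase_fungi at 0.11 (0.01 without JC replicate 6), endochitinase at 0.01 and exochitinase at -0.01. The single pectin member, pectinase, was at 0.03. Lignin and vanillin degradation had 2 of 6 above 0, with vdh of vanillin dehydrogenase at 0.14, the vanillate demethylase gene vanA at -0.03, the peroxidase genes mnp at -0.18 and lip at -0.04, and phenol_oxidase at -0.02. Both glyoxylate cycle genes, AceB and AceA, were at -0.01. Adjusted over the list alone, 0 members were called in any of these 8 lists, as over all families, and aclB and amyX had an unadjusted limma p under 0.05 (0.0172 and 0.0345). The signs of rubisco, CODH, amyA and phenol_oxidase turned under 3 of the 4 other ways of scaling and combining probes, and with the mean over detected probes aclB, apu, ara_fungi, xylanase, xylA, exoglucanase, endoglucanase, cellobiase, acetylglucosaminidase, chitin_deacetylase_fungi, endochitinase, pectinase and vdh were below 0. Of these aclB, ara_fungi, xylanase, exoglucanase, cellobiase, acetylglucosaminidase and endochitinase were below 0 with quantile normalization too. Without scaling pcc, FTHFS, nplT, mannanase, CDH, exochitinase, vanA, mnp, lip, AceA and AceB were above 0. Quantile normalization also put FTHFS above 0. Scaling to the median of shared probes also put mannanase, CDH, exochitinase, vanA, lip, AceA and AceB above 0. The signs of rubisco, CODH, FTHFS, xylA, endoglucanase, endochitinase, exochitinase, AceA and AceB turned when a certain JC sample was left out.

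Phosphorus and sulfur genes gave no calls either. The polyphosphate genes ppk (-0.04) and ppx (-2.1e-04) and phytase (-0.04) were below 0, and above 0 without scaling, and the sign of ppx also turned when 1 JC sample was left out. Scaling to the median of shared probes also put ppk, ppx and phytase above 0, and quantile normalization ppx and phytase. Sulfur cycling had 5 of 9 members above 0, with AprA, the adenylylsulfate reductase of sulfate reducers, at 0.15 (limma p = 0.0263, adjusted p = 0.448). Both dissimilatory sulfite reductase genes, dsrB and dsrA, were at 0.06, and CysI at -0.56 with a 95% interval of -1.37 to 0.24, where 1 GM sample was at 0 and the log2 ratio of the mean shares was -0.17. Adjusted over the list alone, 0 members of either list were called, and AprA was the 1 with an unadjusted p under 0.05. With the mean over detected probes AprA, dsrA and dsrB were below 0.

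Stress genes of cold, oxygen and nutrients had members on both sides. The cold shock gene cspA was at 0.23 (95% interval 0.04 to 0.42, limma p = 0.0165, adjusted p = 0.378) and above the JC mean in 12 of 15 GM samples. Of the cold and heat shock list 7 of 9 members were above 0, while the heat shock regulator hrcA was at -0.04 and the chaperone gene groEL at -0.07. The membrane sensor gene desK was at 0.56 on the log2 scale with a 95% interval of -0.37 to 1.48 (0.05 without JC replicate 2), but its mean share was lower at GM (0.00242%) than at JC (0.00272%). Oxygen limitation and oxidative stress had 7 of 14 above 0, with the cytochrome oxidase genes cydA at 0.13 (p = 0.00757, adjusted p = 0.378) and cydB at 0.09, the nitrate reductase subunit narH at 0.09 and the catalase gene katE at -0.04 (p = 0.0422). Nutrient limitation and osmotic stress had 6 of 13 above 0, with the phosphate transport genes pstS at 0.16 (p = 0.0116), pstA at 0.02 and pstB at -0.06 (p = 0.0278), and bglP at 0.18. Adjusted over the list alone, 0 members were called in these 3 lists, as over all families, where 1, 2 and 2 members had an unadjusted limma p under 0.05. With the mean over detected probes cspA, desK, cydA, cydB, narH, pstS, pstA and bglP were below 0. The sign of bglP turned with quantile normalization as well, and that of katE without scaling, with scaling to the median of shared probes and with quantile normalization. Those of hrcA, groEL and pstB turned without scaling. That of hrcA also turned with scaling to the median of shared probes, and that of groEL with quantile normalization.

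Resistance, pollutant and fungal genes gave no calls between GM and JC. In antibiotic resistance 6 of 10 members were above 0, with the small efflux pump family SMR_antibiotics at 0.11 (limma p = 0.00645, adjusted p = 0.378), Van at 0.33, catB at 0.03 and B_lactamase, an enzyme family that opens penicillins, at -0.23 (p = 0.0133; -0.13 without JC replicate 4). In metal resistance 20 of 33 were above 0, with the lead transporter gene pbrT at 0.28 (p = 0.00432, adjusted p = 0.346), the mercury transporter gene merT at 0.24 (p = 0.0128), TerC at 0.08 and TerD at -0.09. In aromatic pollutant degradation 15 of 44 were above 0 and 29 below, with bco at 0.11 (p = 0.00876, adjusted p = 0.378), nahA of naphthalene degradation at -0.07, hmgC at 0.08 and tutFDG of toluene degradation at -0.06. Among fungal genes 43 of 58 were above 0, with alpha_galactosidase_fungi at 0.29 (p = 0.00977, adjusted p = 0.378), cutinase_fungi at 0.09 (p = 0.0216), cellobiase_fungi at 0.12 and phospholipase_B_fungi at 0.18. Adjusted over the list alone, 0 members were called in any of these 4 lists, as over all families, with 2, 2, 1 and 2 members at an unadjusted limma p under 0.05. With the mean over detected probes SMR_antibiotics, Van, catB, TerC, bco, hmgC and the 4 named fungal families were below 0. Quantile normalization put B_lactamase and tutFDG above 0, and catB, alpha_galactosidase_fungi and phospholipase_B_fungi below 0. Without scaling TerD, nahA and tutFDG were above 0.

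**Figure D3:**
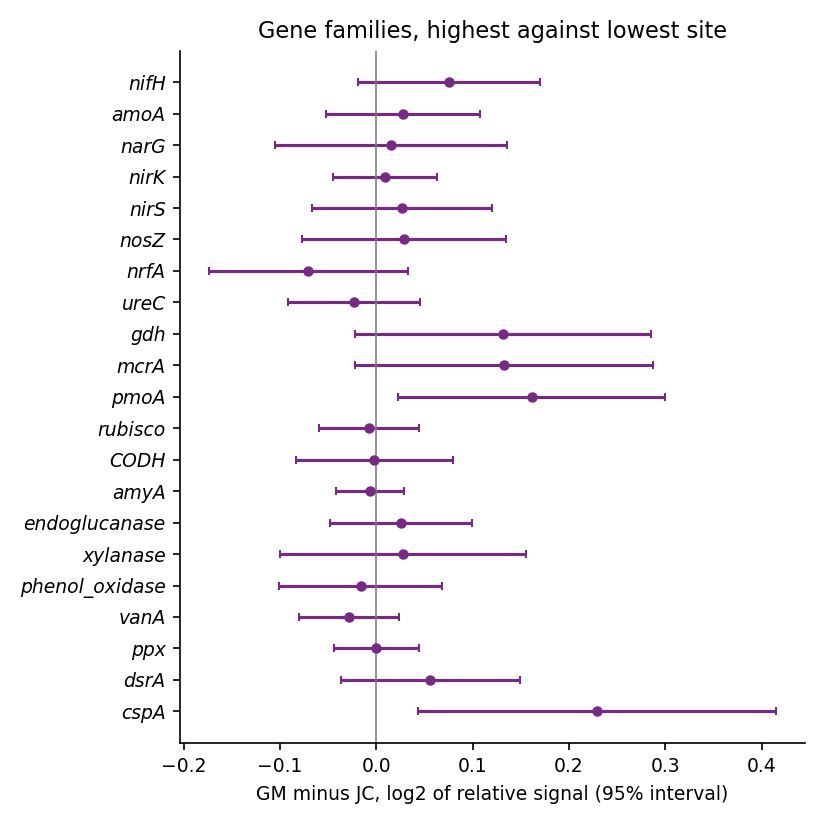
Log2 difference in percent of signal between GM (n = 15) and JC (n = 8) for marker gene families (y axis), as points with 95% limma intervals on the x axis. The intervals of pmoA (0.02 to 0.30) and cspA (0.04 to 0.42) leave out 0, and neither family passes the adjusted threshold.

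As whole groups, probes of stress genes took a smaller share of the signal at GM than at JC, and probes of viruses a larger one. Of the 876 virus probes 291 were for RNA viruses, although genomic DNA was measured. The stress category fell from 21.2% ± 0.172 at JC (SD, n = 8) to 21.0% ± 0.135 at GM (n = 15), a difference of -0.225 percentage points (95% interval -0.354 to -0.0954, exact permutation p = 0.00225, adjusted p = 0.0315 over 14 categories), and 1 of 15 GM samples lay above the JC mean. Probes from the domain of viruses rose from 0.643% ± 0.0469 to 0.702% ± 0.0439, a difference of 0.0584 percentage points (exact permutation p = 0.00826, adjusted p = 0.0496 over 6 domain sets), with 13 of 15 GM samples above the JC mean. Stress took 20.965% at LK, 21.022% at JH, 21.038% at HJ and 21.048% at LS, against 20.956% at GM, so JC lay above the other 5 sites, and viruses took 0.689%, 0.677%, 0.667% and 0.673% at the same 4 sites. Over all 6 sites neither passed (permutation F test, adjusted p = 0.459 for stress and 0.516 for viruses). The virus category, nearly the same probes, had an adjusted p of 0.0578 over the categories. Of the 24 gene lists 0 passed, with the smallest exact permutation p for carbon fixation (2.41% at GM and 2.48% at JC, p = 0.0371) and methane cycling (0.339% and 0.311%, p = 0.0389), both with an adjusted p of 0.436. Bacteria, archaea and fungi had close shares, with 87.4% and 87.6% for bacteria, 1.88% and 1.88% for archaea and 7.52% and 7.35% for fungi at GM and JC. The stress call ended when lists and categories were adjusted together (adjusted p = 0.0854) and when shares of detected probes replaced shares of signal (difference -0.0443, adjusted p = 0.778). The virus call ended with shares of detected probes (difference 0.0536, adjusted p = 0.603) and without the 10 samples of high summed intensity (difference 0.0521, adjusted p = 0.164). It also ended without the 10 samples apart on the first component (difference 0.0510, adjusted p = 0.0573). Both calls ended without scaling, where the stress category was higher at GM than at JC.

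**Figure D4:**
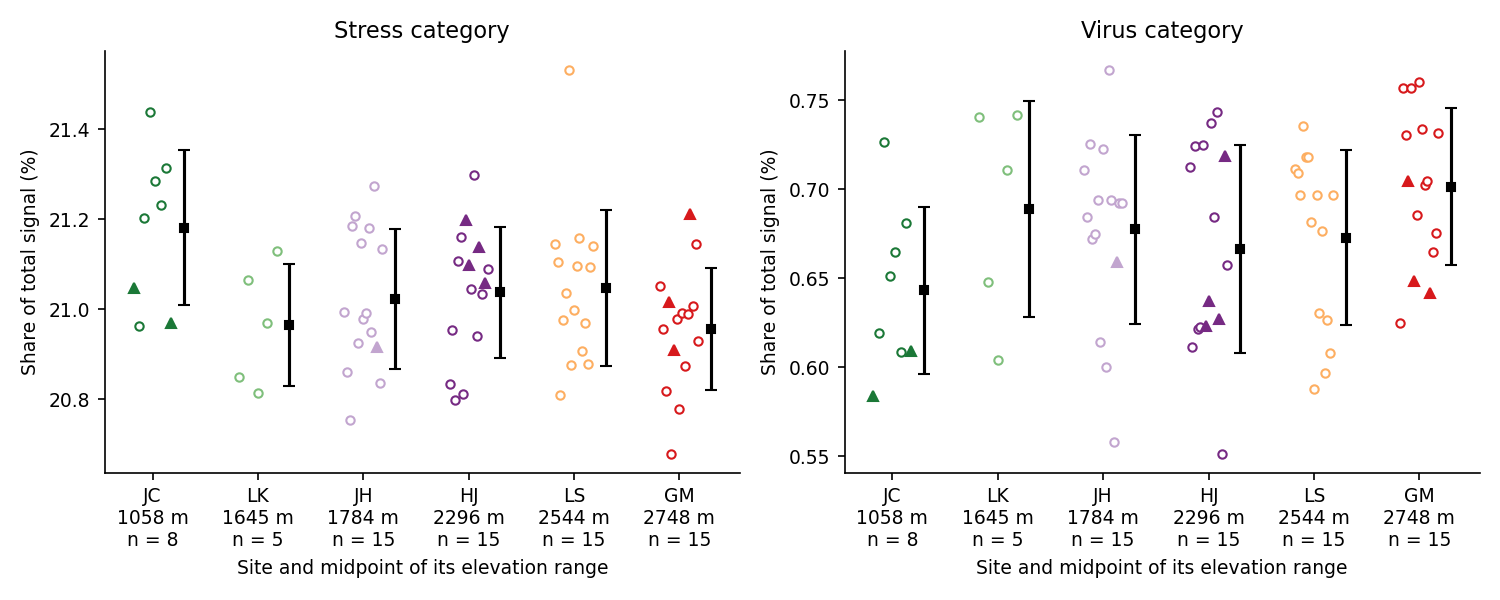
Share of total signal in percent (y axis) of the stress and the virus category in each sample, by site from the lowest to the highest (x axis). Circles are samples, triangles the 10 samples with a summed intensity above 1000 units, and black squares with bars the site mean and SD.

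Of the 5 steps between sites next to each other, the highest one gave a called family. From LS to GM the family spe, which the table files under secondary metabolism, fell from 0.182% ± 0.0101 to 0.163% ± 0.0115 of the signal (SD, n = 15 each), a log2 difference of -0.16 (95% interval -0.24 to -0.09, limma adjusted p = 0.0290), and all 15 GM samples lay below the LS mean. It was the 1 family called of 528 in that step, where 77 had an unadjusted p under 0.05 (49 higher and 28 lower), and the permutation test called it too (adjusted p = 0.0475, 78 families unadjusted). Next to it, named after their values were seen, came replicase_Necrovirus, a plant virus polymerase family, at 1.26 (adjusted p = 0.0516) and nasA, an assimilatory nitrate reductase family, at 0.12 (adjusted p = 0.0638). Of replicase_Necrovirus 2 LS samples were at 0, the log2 ratio of its mean shares was 0.74, and with a smaller pseudocount it was at 1.58 (adjusted p = 0.0836). Both replicase_Necrovirus and nasA were below 0 with the mean over detected probes, where the median family was at -0.23. The call of spe ended with scaling to the median of shared probes (-0.10, adjusted p = 0.264), quantile normalization (-0.16, 0.147), the mean over detected probes (-0.26, 0.132), probes with signal in all samples (-0.28, 0.118), the number of detected probes as a term (-0.14, 0.0912) and without the samples of high summed intensity (-0.15, 0.130). Without scaling spe was at 0.54, where the median family was at 0.71.

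The lower steps gave no calls in limma. LK against JC had 22 families at an unadjusted p under 0.05, led by nagK, named after its values were seen, with 0.0887% ± 0.00186 at LK (SD, n = 5) and 0.0976% ± 0.00375 at JC (n = 8), a log2 difference of -0.14 (limma adjusted p = 0.130). JH against LK, 2 sites at nearly the same elevation, had 15 such families, HJ against JH 27 and LS against HJ 45, where 26.4 are expected by chance. The lowest adjusted p in these steps were 0.953, 0.851 and 0.120. The permutation test per family called 0 in each of the 4 steps, with 20, 11, 24 and 40 families unadjusted from the lowest step up. For LK against JC its lowest adjusted p was 0.410, the smallest that the 1287 regroupings allow for a lone family. A lone family could therefore not be called in that step, and its 0 decides nothing.

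Over all 6 sites the F test called 0 of 528 families in limma, with 38 at an unadjusted p under 0.05. The family closest to the threshold was nagK (adjusted p = 0.0584), which ran from 0.0887% of the signal at LK to 0.0976% at JC. The permutation test per family called nagK (adjusted p = 0.0475) and had 39 families unadjusted.

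For a steady change with elevation, 0 of 528 families passed in limma on the 6 site means, with a lowest adjusted p of 0.132. An unadjusted p under 0.05 was found for 68 (35 with positive and 33 with negative slopes), where 26.4 are expected by chance. As many were found in 2 of 100 splits of the samples, the real one included, a test chosen after the result was seen. Splitting samples removes every difference between sites, so this count cannot tell elevation from other differences between the 6 sites. The smallest p among positive slopes belonged to RdRp_Nepovirus, a plant virus polymerase family, with 0.15 log2 units per 1000 m, followed by single_strand_annealing_protein (0.09), pabA (0.13), vdh (0.09) and coat_unassigned_Secoviridae (0.33). Among negative slopes it belonged to coat_Tritimovirus, a plant virus coat family, with -0.22, followed by tmoABE of toluene degradation (-0.24), the phage family terminase_small_subunit (-0.50, with 2 HJ samples and 1 GM sample at 0), xylG (-0.11) and vir (-0.13). Without LK, coat_Tritimovirus (-0.24, adjusted p = 0.0382) and terminase_small_subunit (-0.56, adjusted p = 0.0319) were called. Among the site means of 24 list shares, detected probes and diversity, 0 of 26 relations passed. For rho, the smallest permutation p that the 720 pairings allow is 0.00278, so a lone relation could not pass over 26 tests. With so few sites, the 0 is not evidence that these measures stay level with elevation. Carbon fixation had a Pearson r of -0.958 (exact permutation p = 0.00556, adjusted p = 0.108) and a Spearman rho of -0.943 (p = 0.0167), and r was -0.979 without JC and GM, with no p computed. The antibiotic resistance list had an r of 0.956 (exact permutation p = 0.00833, adjusted p = 0.108) and a rho of 0.943 (p = 0.0167), and r was 0.979 without JC and GM, with no p computed. Carbon fixation took 2.48% ± 0.0602 of the signal at JC (SD, n = 8), 2.40% ± 0.0646 at LS and 2.41% ± 0.0777 at GM (n = 15 each), and antibiotic resistance 3.99% ± 0.0622, 4.08% ± 0.110 and 4.06% ± 0.135. Members of both lists went both ways. In carbon fixation pcc, with 650 of 1353 probes, had a slope of -0.05, FTHFS -0.03, rubisco -0.02, CODH 0.03 and aclB 0.06. In the antibiotic list SMR_antibiotics, with 821 of 2305 probes, had a slope of 0.06, while B_lactamase had -0.10.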

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

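The tests on samples with a high summed intensity, on samples apart on the first component and on how often RNA virus probes had signal were chosen only after the result was seen, while the test of RNA virus values near the lower limit was written before it was run. In JC and LK, the sites with 10 or fewer samples, a value was set apart when its gap to the nearest other sample, as a share of the site's range, exceeded Dixon's 95% limit. Of 260 groups tested 28 held such a value, where chance sets apart about 1 in 20, and the measures overlap, so they are not 28 independent findings.

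LK replicate 3 held 12 of these values and had signal on 23821 probes, the fewest of the 73 samples. Ammonia oxidation stood out there, with amoA at 1.51% of the signal (1.26 to 1.31% in the other LK samples) and the nitrification and anammox list at 1.56%. The urease family ureC took 1.15% (0.966 to 1.01% in the others), ara_fungi, filed under carbon cycling, 0.226% (0.124 to 0.130%), CDH 0.185%, desK 0.00468% and the hemicellulose list 1.33%. The virulence category took 4.65% there. Lower than in the other LK samples were AceA of the glyoxylate cycle at 0.557%, the nitrate reductase gene napA at 0.144% (0.210 to 0.231%), the phosphate-binding gene pstS at 0.191% and the table's category of other functions at 1.70%. LK replicate 2 held vanA at 0.474%, acetylglucosaminidase at 0.474% and cutinase_fungi, the lowest of its site, at 0.137%. LK replicate 4 held the nitrogen category at 8.43% and pstA, the lowest of its site, at 0.7103%.

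JC replicate 4 held the beta-lactamase family B_lactamase at 0.106% (0.0511 to 0.0728% in the other JC samples), AceB at 1.03% and tutFDG at 0.215%, each the highest of its site, and endoglucanase at 0.173% and vanA at 0.421%, each the lowest. JC replicate 1, one of the samples with a high summed intensity, held FTHFS, a gene of acetogens, at 0.184% (0.0529 to 0.0733% in the others) and nrfA at 0.410% (0.261 to 0.318%), both the highest, and catB at 0.361%, the lowest. Single values set apart were bglP at 0.0314% in JC replicate 6, xylA at 0.362% in JC replicate 7 and, as the lowest, the lignin peroxidase family lip at 0.0640% in JC replicate 8.

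In 10 samples the summed intensity lay between 1647.4 and 2817.9 in units of 1000000, against at most 648.62 in the other 63 samples. Of the 10, 4 had signal on more probes than the median of the other samples of their site. This count cannot decide whether more DNA lay on the array. The rule for calling a probe detected is unknown, and the lowest intensities rose with the totals (median 8825 against 1035 in the other samples). A property of whole sites is argued against, since 4 sites held both such samples and others. A higher gain or labelling of the whole array may be the source, since the median of the lowest intensities was 8.52 times that of the other samples, beside 6.16 times for the totals. The labels give neither scanner settings nor labelling yields, so this stays a hypothesis.

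Another 10 samples, 1 of JH and 3 each of HJ, LS and GM, scored above 0.2 on the first component of probe signal (lowest score 0.246, next sample 0.0606). A high brightness of the array is argued against, since 0 of them were among the samples with a high summed intensity, and a property of whole sites too, since 4 sites held both such samples and others. A low brightness may contribute, since all 10 had a summed intensity (200.57 to 248.14) below the median of the other samples of their site, though 3 other samples with totals as low scored -0.0806 to -0.0294. More or less of some genera may contribute, as genera held 5.43% of the variance of probe loadings, against 4.49% on average and 5.24% near the top of 1000 shuffles, but gene families (4.65%, against 3.36% and 3.99%) and phyla (0.604%, against 0.245% and 0.439%) also lay above theirs, so genera cannot be told apart from these groupings. The labels give no batch, and a difference in soil between plots of a site stays untested.

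Probes for RNA viruses had signal although the labels name genomic DNA as the measured molecule. They had signal in 43.45% of their values, against 42.5% for probes of other viruses and 60.7% for all probes. Signal that does not need the target of the probe may account for part of this. Values near the lower limit of detection cannot be told apart from others here, since the median RNA virus value lay at percentile 32.8 of its sample, between the bounds set for either answer. Every RNA virus family named in the text shares this limit, and no biological explanation was tested.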

How the results depend on the processing

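The alternatives without samples of high summed intensity, samples apart or a JC sample, with added terms and with lists and categories adjusted together were chosen after seeing the data, and the others before. The deposited table holds no background signal, so how far weak values lie above it is unknown. Results over families depend on the scaling, as sums without scaling move the median family by 0.21 (GM against JC), -0.20 (LK against JC), 0.54 (HJ against JH), -0.84 (LS against HJ) and 0.71 (GM against LS) on the log2 scale, and the mean over detected probes moves it by -0.13 (GM against JC), 0.15 (HJ against JH) and -0.23 (GM against LS). Where a value changed, the cause was not tested unless stated. For the named families 1929 values kept their sign and their side of the threshold, 214 turned sign without being called, 11 became called, 6 were no longer called and 1 reversed, over 92 results.

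GM against LS, with 1 called family, had 0 with scaling to the median of shared probes, with the mean log2 of detected probes, without the samples of high summed intensity and with the number of detected probes as a term. It had 4 with probes detected in 3 samples of a site (spe, replicase_Necrovirus, nasA and nagK), 2 with trend and robust in eBayes, 7 without the 10 samples apart on the first component (spe, replicase_Necrovirus, nagK, CysJ, SilA, ABC_transporter_III and protease_serine_fungi) and 3 with both sets of samples as terms (spe, replicase_Necrovirus and nagK). The count stayed at 1 without scaling, with quantile normalization and with probes detected in all samples, but the called family was replicase_Necrovirus in the first case and rgh_fungi in the others. LS against HJ had 1 called family without scaling (replicase_Necrovirus), with quantile normalization and with probes detected in all samples (rgh_fungi), and without the samples apart (nbaC_fungi). The 6-site test had 1, nagK, with probes detected in 3 samples of a site, in the permutation test, without the samples apart and with both sets as terms. GM against JC had 2, nagK and terminase_large_subunit, without the samples apart and 1, nagK, with both sets as terms. LK against JC had 1, nagK, in both of these. Terms or samples taken from the same probe values make such calls too easy.

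Replicate numbers recur at every site, but samples with the same number shared no more than the number: the mean correlation of their residuals was 0.0188, against 0.00884 for other pairs, and 5 of 73 samples were closest to one with their own number. With the replicate block, the 6-site test called 1 family (nagK), LK against JC 1 (nagK) and GM against LS 2 (spe and replicase_Necrovirus).

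Of the categories, with 1 called, 0 passed without scaling, with shares of detected probes and with lists and categories adjusted in one family, where more tests share the correction. Without the samples apart 2 passed, stress and energy process. Of the domain sets, with 1 called, 0 passed without scaling, with shares of detected probes, without the samples of high summed intensity and without the samples apart, where the virus difference was 0.0521 and 0.0510 in the last 2 cases against 0.0584. Without scaling the stress category was higher at GM by 12.983 units of 1000000, since sums follow the totals, and spe reversed to 0.54, below the median family at 0.71. Site accounted for a share of 0.11652 of the variation without the samples apart (adonis2, p = 0.0261), where 8.06% is expected by chance. With both sets as terms it accounted for 0.0682 (p = 0.0847), for which no chance share was computed.

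Leaving out each JC sample gave 0 to 1 called families for GM against JC, with 1, terminase_large_subunit, without JC replicate 3. Leaving out each LK sample kept 0 calls in LK against JC, JH against LK and the 6-site test, and community R2 between 0.0834 and 0.0905. Leaving out each site in turn, families with a trend numbered 0 to 2, with 2 without LK. The correlation of detected probes with elevation ran from -0.449 to 0.336, highest without LS, and that of Shannon diversity from -0.483 to 0.223.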

Other observations

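The tests of the parts of the viruses, of fungal families on one side and of splits of the samples were chosen only after the result was seen, while the count of virus families on one side was written before it was run. Within the viruses, probes that are not from RNA viruses took 0.475% ± 0.0310 of the signal at GM (SD, n = 15) and 0.428% ± 0.0252 at JC (n = 8; exact permutation p = 0.00146, adjusted p = 0.00292 over both parts). RNA virus probes took 0.226% ± 0.0152 and 0.215% ± 0.0277 (exact permutation p = 0.242), and whether the parts differ from each other was not tested. The parts were taken from the virus set after it was called on the same samples, and their p-values do not account for that choice. They were not computed under the alternatives that ended the virus call, so they are no firmer than that call. The energy process category took 0.966% ± 0.0321 at GM and 0.936% ± 0.0233 at JC (exact permutation p = 0.0342, adjusted p = 0.160), with 12 of 15 GM samples above the JC mean.

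At LS, CysJ, a subunit of assimilatory sulfite reductase, took 0.556% ± 0.179 of the signal, against 0.733% ± 0.143 at HJ (SD, n = 15 each), a log2 difference of -0.44 that did not pass (limma adjusted p = 0.317). From LS to GM it was called without the 10 samples apart on the first component (0.51, limma adjusted p = 0.0327). The plant virus family replicase_Necrovirus took 0.00329% ± 0.00204 at LS and 0.00547% ± 0.00126 at HJ (limma adjusted p = 0.120). Both were named after their values were seen.

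Families of one kind lay mostly on one side between GM and JC. Of 58 fungal families 43 were higher at GM (permutation p = 0.228), and of 54 families of the virus category 40 were (permutation p = 0.0726, adjusted p = 0.145). Neither count was beyond what regrouping the samples gives.

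For GM against LS, 5 of 100 splits of the samples, the real one included, gave at least as many called families as the 1 called, and the highest of the other splits called 39, so chance could not be excluded. Where the real split called 0, all 100 splits gave as many by construction, so these splits say nothing about chance. The highest other split called 18 families for the 6 sites, 1 for GM against JC, 4 for LK against JC, 38 for JH against LK, 23 for HJ against JH, 65 for LS against HJ and 2 for the elevation trend. Splits that call many families point to a structure among the samples or to families that move together, which were not separated. At an unadjusted p under 0.05, as many families as in the real split were found, the real one included, in 18 of 100 splits for the 6 sites, 11 for GM against JC, 45 for LK against JC, 54 for JH against LK, 37 for HJ against JH, 27 for LS against HJ, 8 for GM against LS and 2 for the elevation trend. The count for the trend treats samples as independent of their site, so it cannot tell elevation from other differences between sites.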
